A study of Drosophila melanogaster with 3 samples.

How the data were processed

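Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos aged 8 to 24 h that carried a transgene for Dbx fused to enhanced green fluorescent protein (eGFP), per the labels. Chromatin was sonicated to fragments of 200 to 800 bp and the fusion protein was recovered with an antibody against GFP, per the labels' descriptions. Another field of the labels names Dbx as the antibody, which was read as the target. The 3 samples are 3 biological replicates of 1 group, numbered as the labels number them. An age field in the labels holds a value that cannot be the age of an embryo in hours, so the age was taken from the source name.

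For each replicate, and for the 3 replicates together, the authors deposited peak lists on the dm6 assembly, ranked and thresholded by the irreproducible discovery rate (IDR), per the text deposited with the libraries. The ranked lists give −log10 of the IDR of each peak as deposited. Each thresholded list was compared with the ranked lists, and every peak in it had an IDR of at most 0.01. The summit offset, in bp from the peak start, is also the authors' deposited value. The signal of each peak is the authors' own enrichment value. It was used only to rank, filter and describe peaks within a list, because nothing in the lists makes it comparable between them. The authors deposited 4 series-level ranked lists and 4 series-level thresholded lists, 1 of the latter named conservative, and that conservative list was taken as the main list before the data were examined. The deposited text derives each series-level list from the alignments of all 3 replicates but does not say which pair or pool of replicates it compares, so the share of its peaks found in a replicate list depends on a step that is not known. The columns of the series-level ranked lists that hold values of unnamed single samples, 8 per list, were not used. The aligner, the peak caller and their versions are not given in the sources used here. Read depth is unknown from the lists, so no interval that needs it is given. A control experiment that the labels mention was not analysed here.

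Coordinates are those of the files on dm6, written 1-based. The Ensembl release 115 annotation and the RefSeq sequence of the same assembly were used. It was checked that no peak or gene reached past the end of its chromosome, and that nearly all annotated start codons read ATG in the sequence. Peaks off chromosomes 2L, 2R, 3L, 3R, 4 and X were left out of every step except the counts of peaks per list. Overlap between lists was 1 bp or more and was set against 1000 random placements of the same peaks on the same chromosomes. Summits were assigned to 1 feature class each, in the order promoter (within 250 bp of a transcription start site, TSS, of a protein-coding gene), 5' UTR, coding exon, 3' UTR, intron and intergenic. Shares were compared with the share of bases by two-sided exact binomial tests with Benjamini-Hochberg adjustment. These tests treat summits as independent and cover counting error over peaks only, so the mean ± SD of the 3 replicate lists is given beside them.

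A gene was counted for a list when it was the nearest protein-coding TSS to at least 1 summit. For each of 12 gene lists this share was compared with 10000 random lists of the same size, matched on the decile of TSS territory (the stretch of chromosome nearer to the gene's TSSs than to any other), as a two-sided permutation test. The smallest p it can give is 0.0002. Fisher's exact test against all other protein-coding genes was run beside it, and calls rest on the matched test with Benjamini-Hochberg adjustment over the 12 lists. Symbols Dl and h of the lists were read as Delta and hry, their names in the annotation. A TSS shared by 2 genes was given to 1 of them, so at head-to-head promoters the nearest gene is only 1 of the candidates.

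The presence of 15 fixed words, on either strand, within 100 bp of each summit was compared with the mean of 2 windows of the same width centred 1000 bp to either side. These windows were not matched to the summits on feature class. A ratio to flanks above or below 1 can therefore also reflect a difference in class, such as promoter against coding exon. The exact McNemar test used 1 of the 2 windows, drawn with a fixed seed, and was adjusted over the words. The windows drawn differ between peak sets, so an adjusted p near the threshold can move with the draw. All reverse-complement collapsed 6 bp words were scanned in the same way. As a second background, each summit window was shuffled once with its dinucleotide counts kept. Flanking windows were not shuffled, so a ratio to shuffled windows also holds how often a word occurs in the genome at large.

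Genes named in the text were chosen by a rule set before the data were examined. They are the nearest genes of the 20 main-list peaks of highest signal that overlap a peak in all 3 replicate lists, up to 4 members of each gene list whose best such peak ranks highest, and Dbx, eve, exex, zfh1, HGTX and vnd whatever their values. The 5 hexamers of highest ratio among those past an adjusted p of 0.05, and the 15 words, were named by the same rule. Other names are said to have been chosen later where they appear.

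The functions were tested on simulated peaks first. With 4000 random summits, 0 of 6 feature classes, 0 of 12 gene lists and 0 of 15 words passed the threshold. These summits were spread evenly over bases, unlike those of the conservative list, of which 51.4% lay at promoters. Gene lists were matched on territory and not on the number of TSSs. The simulation therefore does not show how the list test behaves when summits gather at promoters of genes with many TSSs. A planted promoter share of 43.8% was recovered as 43.8%, and a planted overlap of 59.7% between a pair of lists as 59.9%. A planted gene list and a planted word were both called. The direction of a gene list was first set by the matched median. It was changed to the matched mean after the results were seen, because a tie with the median read as a change of direction, and no p-value changed. Alternatives covered the peak set, the overlap rule, the promoter width, the assignment of peaks to genes, the word window and its background, and leaving out each replicate in turn. Leaving out a replicate meant using the peaks shared by the other 2 lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.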

Results

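Binding of a Dbx-eGFP fusion protein was mapped by anti-GFP ChIP-seq in whole Drosophila embryos of 8 to 24 h, in 3 biological replicates of 1 group. Dbx is a homeodomain transcription factor of interneurons of the embryonic nervous system. With no second group, the comparisons are between replicates and between bound sites and the genome around them. The 3 thresholded replicate lists held 3701, 3353 and 2519 peaks, a mean of 3191 ± 607 (SD, n = 3). The conservative list, which the deposited text derives from the alignments of all 3 replicates without saying which pair or pool of them it compares, held 4943 peaks with a median width of 400 bp, which covered 1737 kb once overlapping peaks were merged into 4575 regions. The longest thresholded list held 6387 peaks. The read depth behind these lists is unknown.

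The strongest sites recurred in every replicate, and the weaker ones less often. The peak of highest signal in the conservative list, in an intron at CG11050 on 2L, also ranked 1 in each of the 3 replicate lists, and those at Ugalt, CG14100 and mRpL41 ranked 2, 3 and 4 in the conservative list and between 2 and 4 in every replicate. Replicate 1 shared 67.2% of its peaks with replicate 2 and 53.9% with replicate 3. Replicate 2 shared 72.9% with replicate 1 and 61.2% with replicate 3, and replicate 3 shared 77.8% with replicate 1 and 80.5% with replicate 2. Random placement gave at most 2.74% in any of the 6 comparisons, and each observed share had the smallest p that 1000 placements can give, 0.001. Among overlapping peaks the authors' signal had a Spearman's rho of 0.697 for replicates 1 and 2, 0.674 for 1 and 3, and 0.749 for 2 and 3, across peaks, which are not independent replicates. Of the 4943 conservative peaks, 1789 (36.2%) overlapped a peak in all 3 replicate lists and 1012 (20.5%) overlapped a peak in none. The mean share of a replicate's peaks found in another replicate was 68.9%, and for the 500 peaks of highest signal of each replicate, against the whole list of the other, it was 99.0%.

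Peaks lay mainly at promoters. No control was analysed, so here and below it is not known how far the peaks are particular to the Dbx-eGFP fusion. In the conservative list 2543 of 4943 summits (51.4%) were within 250 bp of a protein-coding TSS, a class that holds 6.26% of bases, which is an 8.22-fold excess. In the replicate lists the promoter share was 52.6% ± 2.13 (SD, n = 3). Introns held 30.5% of summits against 40.9% of bases, and intergenic sequence 13.9% against 31.1%. Coding exons held 1.74% of summits against 15.7% of bases, and 3' UTRs 1.07% against 4.81%. In the replicate lists these shares were 30.3% ± 1.82 for introns, 14.0% ± 1.13 for intergenic sequence, 1.02% ± 0.319 for coding exons and 0.905% ± 0.363 for 3' UTRs (SD, n = 3). Without replicate 1, 2 or 3 the coding exon share was 0.341%, 0.301% and 0.402%, and the 3' UTR share 0.585%, 0.652% and 0.684%, further below their shares of bases. All 4 deficits passed the exact binomial test, with adjusted p of 6.85e-51 for introns, 1.80e-172 for intergenic sequence, 1.74e-241 for coding exons and 8.99e-49 for 3' UTRs, and the p of the promoter excess was too small for double precision. The share in 5' UTRs outside promoters, 1.29%, did not differ from their 1.34% of bases (exact binomial adjusted p = 0.853). The median summit lay 225 bp from the nearest TSS. Promoter summits had a median position 50 bp upstream of the TSS, and 70.6% of them were upstream.

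**Figure D1:**
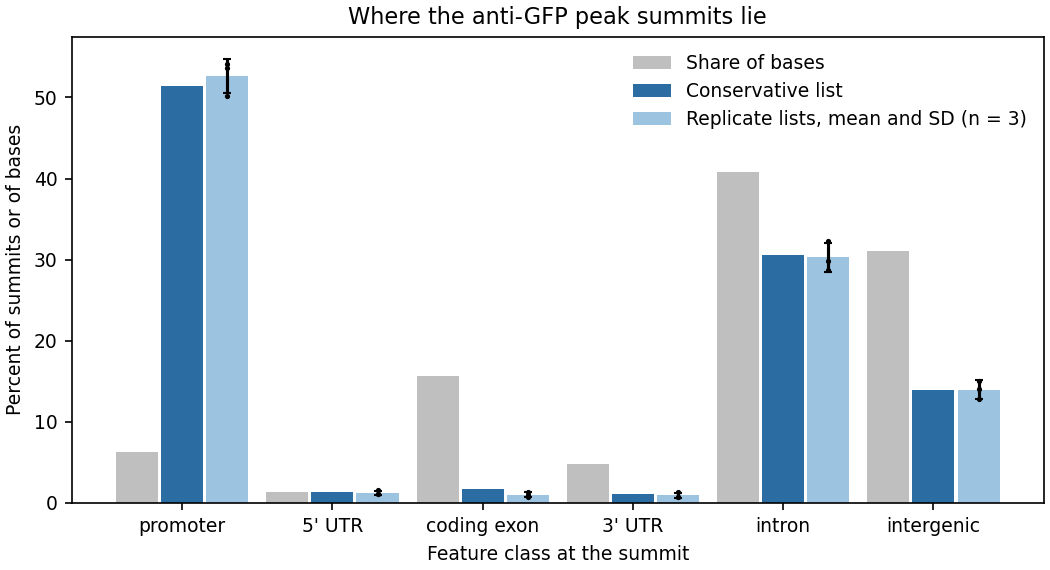
Percent of peak summits in each feature class in the conservative list, the mean of the 3 replicate lists with its SD (points are single replicates), and the percent of bases of the class. Promoters hold 51.4% of summits and 6.26% of bases, while coding exons, introns and intergenic sequence lie below their share of bases.

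Most of the sites of highest signal were in promoters, and most of the others in introns. Of the 20 highest conservative peaks present in all 3 replicates, 12 had their summit in a promoter, 7 in an intron and 1 in intergenic sequence. The promoter summits were nearest to Ugalt (a UDP-galactose transporter), CG14100, mRpL41 (a mitochondrial ribosomal protein), CG5611, Tcs5, eIF6 (a factor of large ribosomal subunit maturation), CG7601, Art3 (an arginine methyltransferase), Atat (an alpha-tubulin acetyltransferase), CenG1A, PNPase (polynucleotide phosphorylase) and CG13390. The intronic summits were at CG11050, Adf1 (a transcription factor), ph-p (a Polycomb group protein), Trl (GAGA factor), CG32772, CG9663 and HmgZ (an HMG-box protein), and the intergenic one was nearest to CG4004. The peak at CG11050 spanned 2L 6612431 to 6613005 with a signal of 3785, that at Ugalt X 2703682 to 2704089 with 3394, that at CG14100 3L 19590424 to 19590807 with 3017, and that at mRpL41 2R 15217562 to 15217965 with 2707. The twentieth, at HmgZ on 2R, had a signal of 1548. In replicate 1 these 20 peaks ranked between 1 and 42, in replicate 2 between 1 and 20, and in replicate 3 between 1 and 27.

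Chromosome 4, which is largely heterochromatic, carried few sites. It held 9 summits (0.182%) against 1.01% of bases (exact binomial adjusted p = 1.36e-11), and 0.229% ± 0.173 in the replicate lists (SD, n = 3). Without replicate 1, 2 or 3 its share was 0.0488%, 0.0501% and 0.161%, each past the test. Among the 500 peaks of highest signal its share was 0.4% and did not pass (exact binomial adjusted p = 0.746). Chromosome arm 2R held 20.9% of summits against 18.9% of bases (exact binomial adjusted p = 0.00145) and X held 16.3% against 17.6% (adjusted p = 0.0371). Neither passed in the peaks present in all 3 replicates, where 2R held 19.6% (exact binomial adjusted p = 0.469) and X 18.4% (adjusted p = 0.403), nor when any 1 replicate was left out. Without replicate 1, 2 or 3, 2R held 18.6%, 19.4% and 20.2% and X 18.9%, 18.0% and 16.7%, so the direction was kept without replicate 3, and for 2R also without replicate 2 and in the peaks present in all 3 replicates. Arms 2L, 3L and 3R did not pass the test, with adjusted p of 0.156, 0.311 and 0.0515. In the longest list all 3 passed, with 18.6%, 22.0% and 22.3% of summits against 17.6%, 21.0% and 24.0% of bases (exact binomial adjusted p = 0.0359, 0.0493 and 0.00482), and 2L also passed in the 500 peaks of highest signal (22.4%, adjusted p = 0.0340) and without replicate 3 (19.9%, adjusted p = 0.00867). The lists lack some peaks past the authors' threshold, of which 97 of 152 for the conservative list and 115 of 181 for the longest were on 3R. With the 152 put back, a setting chosen after the data were seen, 3R held 23.9% and its low share in the conservative list was gone (exact binomial adjusted p = 0.935), and for the longest list this was not run.

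Ribosomal protein genes stood furthest above chance among the 12 gene lists, and chemoreceptor genes furthest below. A summit was nearest to 63 of 85 ribosomal protein genes (74.1%), where matched random lists had a median of 18.8%, and to 3 of 119 odorant and gustatory receptor genes (2.52%), where they had 23.5%. Both had the smallest p the permutation test can give, 0.0002, and an adjusted p of 0.0012. Over all protein-coding genes 3260 of 13945 (23.4%) were nearest to a summit. In the replicate lists the ribosomal protein share was 69.0% ± 7.19 and the chemoreceptor share 1.68% in each of them (n = 3). The ratio to the matched mean was 3.84 for ribosomal protein genes and 5.57, 5.92 and 5.61 without replicate 1, 2 or 3, and for chemoreceptor genes 0.107 and 0.0695, 0.0727 and 0.122, with both lists past the test each time. The highest ribosomal protein sites were promoter summits at RpL7 on 2L, RpS27 on 3R, RpL23A on 3L and RpL32 on 3R, with signal ranks 95, 97, 128 and 153 of 4943. They lay 22 bp downstream, 1 bp downstream, 107 bp upstream and 125 bp upstream of the nearest TSS. The only chemoreceptor gene with a peak present in all 3 replicates was Gr89a, whose summit was intergenic and 1383 bp from its TSS. Among the 500 peaks of highest signal the chemoreceptor share was 0.0% where the matched mean was 3.32%, and did not pass the permutation test (adjusted p = 0.199). With summits outside promoters alone, a split chosen after the data were seen, the ribosomal protein share was 5.88% (matched mean 5.86%, permutation adjusted p = 1.0).

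Among the neural lists, in the conservative list, genes of axon guidance were nearest to a summit more often than matched random lists. The genes that set neuroblast and neuron identity were not, and the neural lists were not tested against each other. A summit was nearest to 20 of 33 axon guidance genes (60.6%, matched median 36.4%, permutation adjusted p = 0.0192). Among them were PlexA (a semaphorin receptor), unc-5 (a netrin receptor), side (a guidance cue of motor axons) and tutl, with best ranks 306, 449, 655 and 1108. The summit at PlexA was in a promoter on chromosome 4, that at side in an intron 30240 bp from the nearest TSS, and those at unc-5 and tutl in intergenic sequence 801 and 377 bp upstream. In replicate lists 1, 2 and 3 the axon guidance share was 60.6%, 45.5% and 27.3% (permutation adjusted p = 0.0008, 0.176 and 0.923), so only replicate 1 passed. In the peaks present in all 3 replicates the share was 21.2% (matched mean 16.8%, permutation adjusted p = 0.968). Without replicate 1, 2 or 3 it was 21.2%, 21.2% and 36.4% where the matched mean was 19.3%, 17.9% and 21.5% (permutation adjusted p = 1.0, 0.867 and 0.165), and among the 500 peaks of highest signal it was 6.06% (matched mean 6.01%, adjusted p = 1.0). As a ratio to the matched mean, this is 1.71 in the conservative list, 1.26 in the peaks present in all 3 replicates, 1.099, 1.182 and 1.692 without replicate 1, 2 or 3, and 1.01 in the 500 highest, so without replicate 3 the call was lost at a similar ratio. With promoter summits alone, a split chosen after the data were seen, the list passed (51.5%, matched mean 20.3%, permutation adjusted p = 0.0016), and with those outside promoters it did not (30.3%, matched mean 26.0%, adjusted p = 0.804). Matching was on territory and not on the number of TSSs, so genes with many TSSs can be hit more often at promoters. The neuroblast list had 5 of 28 genes (17.9%, matched median 32.1%, permutation adjusted p = 0.226), with intronic peaks in all 3 replicates at brat (rank 244) and grh (rank 1648). The neuronal transcription factor list had 6 of 26 (23.1%, matched median 34.6%, permutation adjusted p = 0.42), and only zfh1 had a peak present in all 3 replicates. Without replicate 1, 2 or 3 it had 3.85% each time, and its ratio to the matched mean was 0.229, 0.240 and 0.200 against 0.688 in the conservative list (permutation adjusted p = 0.335, 0.384 and 0.165). Genes of neuronal function had 6 of 30 (20%, matched median 30.0%, permutation adjusted p = 0.347), among them elav (a pan-neuronal RNA-binding protein, rank 83), Syx1A (a syntaxin, rank 793) and sei (a potassium channel, rank 1665). Glial genes had 5 of 11 (45.5%, matched median 27.3%, permutation adjusted p = 0.347), with moody (a receptor of the blood-brain barrier glia, rank 73) and pnt (rank 996) highest.

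Outside the nervous system, genes of segment patterning and signalling passed the test in the conservative list and those of muscle fell just short of it there. Those of epidermis, gut, fat body and blood did not pass. The ratio to the matched mean was 1.62 for signalling genes and 1.65 for muscle genes, and these lists were not tested against each other. A summit was nearest to 19 of 36 segment and signalling genes (52.8%, matched median 33.3%, permutation adjusted p = 0.0438). The highest were spi (an EGF receptor ligand, rank 368) at its promoter, aos (an inhibitor of the same receptor, rank 463) and sog (a BMP antagonist, rank 719) in introns within the genes, and sty (Sprouty, rank 978), whose summit lay 7888 bp upstream of its TSS, outside the gene and in an intron of another. This call was lost in the peaks present in all 3 replicates (22.2%, matched mean 14.9%, permutation adjusted p = 0.711) and without replicate 1, 2 or 3 (19.4%, 19.4% and 33.3%, matched mean 17.1%, 16.2% and 19.2%, adjusted p = 1.0, 0.867 and 0.165). It was also lost when only summits within 1000 bp of a TSS were counted (44.4%, matched mean 25.9%, permutation adjusted p = 0.0648) and when summits in the gene body or 2000 bp either side were (52.8%, matched mean 37.1%, adjusted p = 0.194). The 500 peaks of highest signal did not give it either (5.56%, matched mean 5.04%, permutation adjusted p = 1.0). In settings chosen after the data were seen, it was lost with 152 further peaks past the authors' threshold put back (52.8%, matched mean 33.0%, permutation adjusted p = 0.0576) and with summits outside promoters alone (33.3%, matched mean 22.3%, adjusted p = 0.345), and it passed with promoter summits alone (41.7%, matched mean 19.1%, adjusted p = 0.0102). It also passed in the longest list (61.1%, matched mean 39.1%, permutation adjusted p = 0.0240). The ratio to the matched mean was 1.62 in the conservative list. Where the call was lost it was 1.49 in the peaks present in all 3 replicates, 1.138, 1.199 and 1.739 without replicate 1, 2 or 3, 1.71 within 1000 bp of a TSS, 1.42 by gene body, 1.103 in the 500 highest, 1.598 with the further peaks put back and 1.496 outside promoters, so some of these calls were lost at a similar ratio. Mesoderm and muscle genes had 17 of 32 (53.1%, matched median 31.2%, permutation adjusted p = 0.0533), led by tin (rank 469, promoter), Mef2 (rank 546, 5' UTR), sls (rank 649, intergenic) and how (rank 1184, intron). In the longest peak list the muscle list did pass (65.6%, matched mean 38.8%, permutation adjusted p = 0.0108), as it did when summits in the gene body or 2000 bp either side were counted (62.5%, matched mean 36.6%, adjusted p = 0.0138). It did not pass in the peaks present in all 3 replicates (15.6%, matched mean 14.1%) or with any replicate left out. In replicate lists 1, 2 and 3 the muscle list had 28.1%, 31.2% and 31.2% and did not pass (permutation adjusted p = 0.971, 0.678 and 0.344). In the 500 of highest signal it lay below the matched mean (3.12% against 4.69%). Homeobox genes as a whole had 20 of 79 (25.3%, matched median 32.9%, permutation adjusted p = 0.29), with Dll, tin, zfh1 and hth highest at ranks 203, 469, 541 and 608. Epidermis and trachea genes had 7 of 19 (36.8%, permutation adjusted p = 0.873), with crb (rank 1400) and grh (rank 1648) highest. Gut, fat body and blood genes had 7 of 20 (35.0%, permutation adjusted p = 0.915), with promoter summits at fkh, ush and bowl at ranks 442, 458 and 674.

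**Figure D2:**
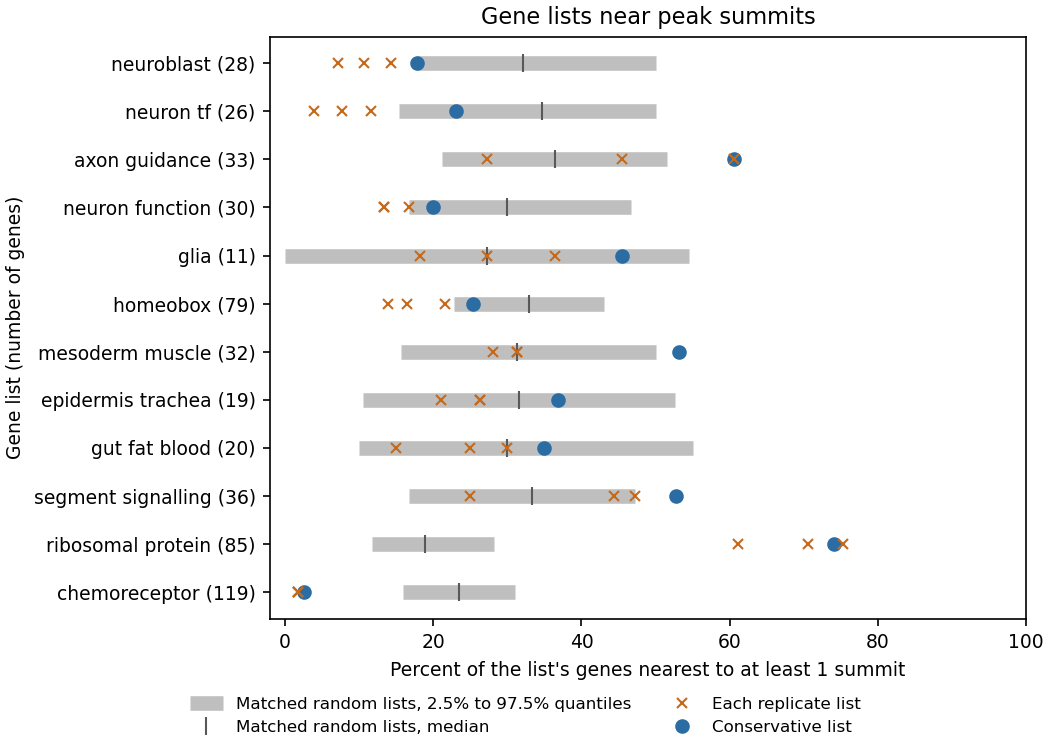
Percent of each list's genes that were nearest to at least 1 summit in the conservative list (circles) and in each replicate list (crosses), with the median and the central range of 10000 matched random lists for the conservative list (grey). Ribosomal protein genes (74.1%) lie above their grey range and chemoreceptor genes (2.52%) below it in the conservative list.

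The Dbx gene itself (FBgn0261723, 3L 1921307 to 1933602, plus strand) held no summit in the conservative list. The 2 conservative summits within 20 kb of it were both at the promoter of Mfap1, at 3L 1941017 and 1941253, with ranks 4228 and 4792. Replicate 2 had 1 summit in an intron of Dbx, at 1928016 (rank 3087 of 3353), and replicate 3 had 1 in a coding exon, at 1925438 (rank 2310 of 2515 on the main chromosomes), while replicate 1 had 0 in the gene. The transgene can carry sequence of its own locus, which limits what peaks inside Dbx show. No conservative summit was nearest to eve (2R 9979319 to 9980795), exex (3L 7948186 to 7951563), HGTX (3L 14583222 to 14599540) or vnd (X 582121 to 598151), which encode homeodomain regulators of the nerve cord, and no replicate summit was nearest to any of the 4. The 4 conservative summits within 20 kb of eve were at promoters of Pdrg1, TER94 and CG12134. By contrast 3 conservative summits were nearest to zfh1 (3R 30765926 to 30789202), a zinc finger homeodomain factor. They lay at its promoter (30765918, rank 3335), in an intron (30781808, rank 541) and downstream of the gene (30789548, rank 2111). Each replicate list had 2 to 4 summits nearest to zfh1, none of them at its promoter.

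Of the 15 fixed words the one with the highest ratio to flanks was TATCGATA, the binding word of the promoter factor DREF, and not a homeodomain word. It stood within 100 bp of 264 summits (5.34%) against 0.506% of flanking windows, a ratio of 10.6 (exact McNemar adjusted p = 3.89e-48). In the replicate lists the ratio was 12.9 ± 3.00 (SD, n = 3). It was 14.0, 16.6 and 19.1 without replicate 1, 2 or 3, 15.1 in the peaks present in all 3 replicates and 7.0 in the 500 of highest signal. By class of summit, a split chosen after the data were seen and not tested, its share was 9.95% at promoter summits against 0.374% in their flanks. It was 1.16% against 0.436% at the 688 intergenic summits and, below the flanks, 0.199% against 0.762% at the 1509 intronic summits. The shares outside promoters rest on few windows with the word. A ratio favours words that are rare in flanks. In the 500 of highest signal TATCGATA stood at 4.2% of summits against 0.6% of flanks. There the homeodomain word TTTATTA stood at 21.2% against 8.8% and the AT-rich ATATAT at 27.8% against 12.6%. The homeodomain core TAATTA had a share of 13.1% against 11.6% in the flanks, a ratio of 1.13 (exact McNemar adjusted p = 0.0437). The word TTATAA, with the same bases in another order, had a higher ratio, 1.30 (exact McNemar adjusted p = 1.46e-04). In the peaks present in all 3 replicates TAATTA had a ratio of 1.501 (exact McNemar adjusted p = 1.94e-05) and TTATAA one of 1.73, in the 500 of highest signal 1.77 (adjusted p = 0.0120) and 2.04, and without replicate 1, 2 or 3 TAATTA had 1.47, 1.44 and 1.36 (adjusted p = 4.55e-06, 2.67e-07 and 0.00455) and TTATAA 1.72, 1.66 and 1.55. In the longest list the TAATTA ratio was 1.07 (exact McNemar adjusted p = 0.405) and with flanks at 500 bp 1.09 (adjusted p = 0.105). Against dinucleotide-shuffled windows the TAATTA ratio in the conservative list was 0.919 (exact McNemar adjusted p = 0.130). That of TTATAA was lower, 0.886, and passed in this direction (exact McNemar adjusted p = 0.0233). In other peak sets, chosen after the data were seen, TAATTA also lay below shuffled windows and did not pass. Its ratio was 0.899 in all 3 replicates, 0.8 in the 500 highest, 0.922 in the longest list and 0.919, 0.904 and 0.937 without replicate 1, 2 or 3. The other homeodomain core, TTTATTA, had a ratio of 1.44 (exact McNemar adjusted p = 3.91e-10) against flanks and 1.05 (adjusted p = 0.411) against shuffled windows. Against flanks it was 1.89 in the peaks present in all 3 replicates, 2.41 in the 500 of highest signal and 1.93, 1.79 and 1.57 without replicate 1, 2 or 3, each past the test. Summit windows had a mean GC content of 40.3% ± 8.95 (SD over 4943 windows), and flanking windows 43.2% ± 9.60. In the 500 summit windows of highest signal it was 35.3% ± 7.13 (SD over windows).

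Of the other fixed words, GAGAG, the core of the GAGA factor site, had a share of 27.4% against 22.2% (ratio 1.24, exact McNemar adjusted p = 2.07e-09), while in the peaks present in all 3 replicates the ratio was 1.02 (adjusted p = 0.965), and without replicate 1, 2 or 3 it was 0.956, 1.04 and 1.15 (adjusted p = 0.761, 0.977 and 0.00481). The AT-rich ATATAT had a ratio of 1.38 (exact McNemar adjusted p = 2.69e-11) and CGCGCG one of 1.51 (adjusted p = 2.49e-04), and in the peaks present in all 3 replicates the latter was 0.842 (adjusted p = 0.965), with 0.953, 1.04 and 1.49 without replicate 1, 2 or 3 (adjusted p = 0.912, 0.978 and 0.0366). Words below their flanks were CACCTG, of Snail and proneural factors (0.689, exact McNemar adjusted p = 1.61e-09), ACAATG, of Sox factors (0.771, adjusted p = 4.59e-05), GGATTA, of Bicoid-type homeodomains (0.792, adjusted p = 0.00126), and CAGGTAG, of Zelda (0.652, adjusted p = 0.0146). In the peaks present in all 3 replicates CACCTG alone of these 4 passed (0.603, exact McNemar adjusted p = 2.26e-06). CAGGTAG was lost there at a similar ratio (0.64, exact McNemar adjusted p = 0.18), ACAATG had 0.846 (adjusted p = 0.0785) and GGATTA 0.996 (adjusted p = 0.856). Without replicate 1, 2 or 3 CAGGTAG had 0.68, 0.536 and 0.441 (exact McNemar adjusted p = 0.532, 0.149 and 0.0124), ACAATG 0.858, 0.825 and 0.783 (adjusted p = 0.167, 0.0192 and 0.0140) and GGATTA 0.842, 0.877 and 0.805 (adjusted p = 0.532, 0.185 and 0.192). Against shuffled windows CACCTG turned direction (1.19, exact McNemar adjusted p = 0.0590) and CAGGTAG did not pass (0.915, adjusted p = 0.752), while ACAATG (0.714, adjusted p = 4.60e-09) and GGATTA (0.668, adjusted p = 3.53e-07) did. On the same background CGCGCG turned direction (0.598, exact McNemar adjusted p = 3.53e-07), and GAGAG (1.57, adjusted p = 1.16e-37) and ATATAT (1.91, adjusted p = 2.80e-42) passed. TTTATGG (0.852), TGACAG (1.11), CAGCTG (1.1) and ATGCAAAT (0.878) did not pass, with adjusted p of 0.193, 0.238, 0.166 and 0.193. CAGCTG passed against shuffled windows (2.85, exact McNemar adjusted p = 1.15e-43) and in the longest list (1.14, adjusted p = 0.00357). Its share in shuffled windows was 3.92% and in flanks 10.1%, so the ratio of 2.85 is not particular to summits. TGACAG, a word of TALE homeodomain factors, passed in the longest list (1.17, exact McNemar adjusted p = 0.00804), without replicate 1 (1.40, adjusted p = 0.00746), without replicate 2 (1.28, adjusted p = 0.0225), within 50 bp of summits (1.27, adjusted p = 0.0223) and with flanks at 500 bp (1.24, adjusted p = 0.00389), but its ratio to shuffled windows was 0.947 (adjusted p = 0.508). TTTATGG passed with 1 summit per run of overlapping peaks, chosen after the data were seen (0.834, exact McNemar adjusted p = 0.0227). CAGGTAG was lost with absent peaks put back, a setting also chosen then (0.638, exact McNemar adjusted p = 0.327). Both ratios lay close to those in the conservative list, 0.852 and 0.652. These 2 changes of call may reflect the flank drawn for each peak, which differs between peak sets. Against flanks not matched on feature class, the hexamer scan gave 408 higher and 637 lower at summits at an adjusted p of 0.05. The 5 of highest ratio were CGATAG (13.5% against 4.46%, ratio 3.02), TATCGA (17.3% against 7.22%, 2.40), ACACTG (17.5% against 7.56%, 2.31), ATCGAT (13.8% against 6.39%, 2.16) and ACAGTG (17.3% against 8.41%, 2.05). TATCGA and ATCGAT lie within TATCGATA, and CGATAG overlaps its end. Each of these hexamers stood at 13.5% to 17.3% of summits and TATCGATA at 5.34%, so most windows with one of them lacked TATCGATA.

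**Figure D3:**
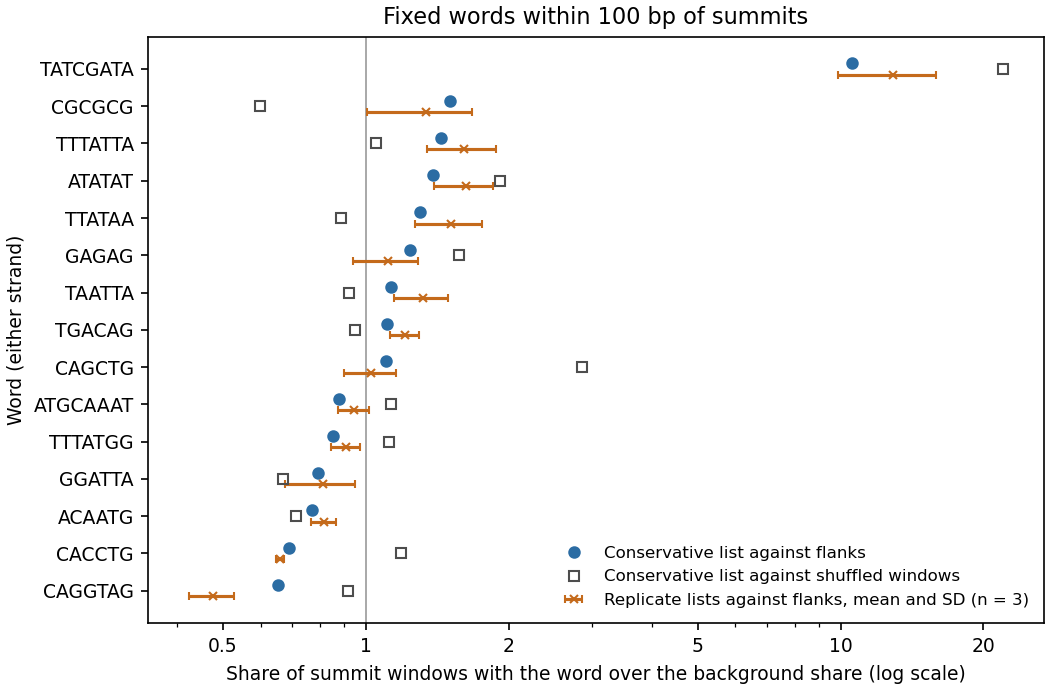
Ratio of the share of summit windows that hold each fixed word to its background share, on a log scale, for the conservative list against flanks (circles) and against dinucleotide-shuffled windows (squares), and for the replicate lists against flanks (crosses, mean and SD, n = 3). TATCGATA is at 10.6 against flanks and 22.0 against shuffled windows, and TAATTA is at 1.13 and 0.919.

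**Figure D4:**
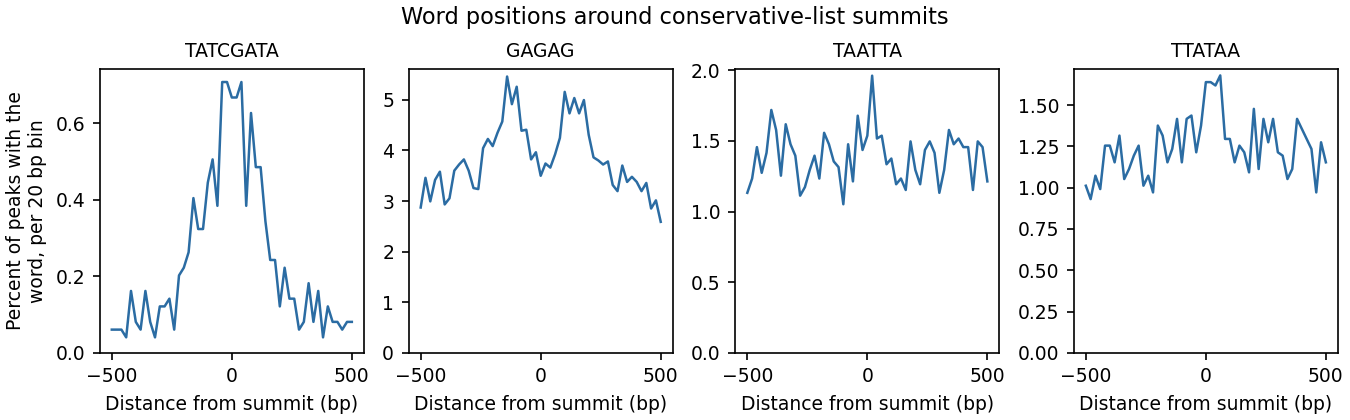
Percent of conservative peaks with a word in each 20 bp bin, by distance from the summit in bp, for TATCGATA, GAGAG, TAATTA and TTATAA. TATCGATA reaches 0.708% of peaks per bin next to the summit and 0.0607% at 500 bp upstream in genome coordinates, while the highest GAGAG bin, 5.46%, is centred at -140 bp and the highest downstream bin, 5.16%, at 100 bp.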

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

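The tests of each explanation below were written down before their results were seen, after the patterns had been seen, while the values of TTTATTA against shuffled windows in other peak sets and the interval over clusters of TSSs were chosen after the result was seen.

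Peaks that passed the reproducibility rate were absent from the thresholded lists, a signal in data that the comparisons did not use. The ranked list behind the conservative list held 5095 peaks at an IDR of at most 0.01, of which 152 were missing from the 4943. Of these 97 (63.8%) were on 3R and 37 (24.3%) on 2L. The strongest was in an intron at cbt (2L 480905 to 481277), with a signal of 2782 that would rank 4, followed by peaks at Lk6, CG18428, larp and trx, all on 3R. The longest run was of 9 peaks at tara (3R 16224366 to 16242809), followed by 7 at crp and 7 at Kdm2. Replicates 1, 2 and 3 had missing peaks of their own that overlapped 111, 100 and 64 of the 152.

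Removal of whole regions may account for the missing peaks. Of the 152, 84.9% had another missing peak directly beside them, against a mean of 5.89% and a highest of 15.1% when as many peaks were drawn at random. Repeats at most missing peaks were argued against, since the median share of soft-masked bases in missing peaks minus that in kept peaks was -0.675 percentage points (95% bootstrap interval -1.88 to 1.45). The bootstrap drew peaks singly, though 129 of the 152 lay in 40 runs, so the interval does not cover dependence within runs. A median over peaks cannot exclude repeats at some peaks or elsewhere in the regions. Per the deposited text the thresholded lists derive from 1 file more than the ranked lists do, of a kind that is not named, and whether it holds the removed regions was not tested. Why those regions would be removed stays open, and no biological explanation was tested.

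Most summits lay at promoters. Binding through the homeodomain word TAATTA at most summits was argued against, since 13.1% of summit windows held it, against 11.6% of flanks. A part through it stays open, because the ratio to shuffled windows cannot decide that. Flanks were not shuffled, so this ratio also holds how often a word occurs in the genome at large. For TAATTA the ratio was 0.919 (95% bootstrap interval 0.831 to 1.01), and for TTATAA, of the same bases, 0.886. For TTTATTA the ratio was 1.05 (0.950 to 1.16), with 1.01 in the peaks present in all 3 replicates (exact McNemar adjusted p = 0.962), 1.05 in the 500 highest (adjusted p = 0.747), 1.09 in the longest list (adjusted p = 0.0659), and 1.16, 1.17 and 1.23 without replicates 1, 2 and 3 (adjusted p = 0.126, 0.122 and 0.0111). Of these 6 only the last passed, and a part through this word stays open because the interval spans the bound of 1.1. Promoter activity alone also stays open, because its test decides nothing. A promoter summit was found at 91.7% of the 36 ribosomal protein genes with TATCGATA or GGTCACAC near a TSS and 67.3% of the 49 without, a difference of 24.3 points (8.38 to 42.1, Fisher's exact p = 0.0087), but GGTCACAC was chosen after the data were seen, from the scan of 8 bp words at these same promoter summits, so a higher share with it follows in part from that choice. The interval also spans the bound of 20 points set beforehand. For these last 2 explanations the verdict was first drawn from the value alone and was made stricter, to need the whole interval, after the values were seen.

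TATCGATA was enriched at summits. Base composition as the cause was argued against, since the word was 22.0 times as frequent as in shuffled windows (95% bootstrap interval 13.4 to 45.2). That promoters hold the word in general does not account for all of it, since 16.4% of TSS with a summit within 250 bp had the word and 6.78% of those without, a ratio of 2.42 (2.19 to 2.67 over single TSSs and 2.14 to 2.72 over clusters of neighbouring TSSs, which share summits). It may account for a part, because TSSs without a summit held the word more often than flanks, at 0.506% in windows of 100 bp either side. TSSs without a summit were not split by activity, so the test does not separate the word from active promoters. Binding near the word, directly or through another protein, is a hypothesis that these lists leave untested.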

How the results depend on the processing

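The settings with absent peaks put back, 1 summit per run of overlapping peaks, 8 bp words, and summits inside or outside promoters alone were chosen after the data were seen. The promoter excess, and the TATCGATA enrichment over all summits, kept their direction and passed in each setting of peak set, window and background run. By class of summit the TATCGATA share lay above its flanks at promoter and intergenic summits but below them at intronic ones (0.199% against 0.762%). Outside promoters these shares rest on few windows with the word and were not tested. Of single values, 3 of 45 for location, 10 of 42 for chromosomes, 12 of 132 for gene lists and 20 of 165 for words turned direction, 0, 6, 17 and 23 kept it but lost the threshold, and 0, 5, 2 and 8 kept it and newly passed. Read depth is unknown, so what it limits was not assessed, and smaller peak sets have fewer summits to test. No paired analysis was possible because there is 1 group.

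Mean replicate overlap was 58.4% with 50% reciprocal overlap and 99.0% for the 500 highest peaks. Mean rho was 0.792 with summits within 100 bp and 0.814 for the 500 highest. Chromosomes past the test numbered 6 in the longest list, 1 in peaks in all 3 replicates, 1 in the 500 highest and 1 to 2 with a replicate left out. Gene lists past it numbered 2 in peaks in all 3 replicates, 1 in the 500 highest, 1 outside promoters and 2 with any replicate left out. Words past it numbered 6 in peaks in all 3 replicates, 6 in the 500 highest and 7 to 10 with a replicate left out. Hexamers higher and lower numbered 193 and 313 in the 500 highest, and 8 bp words higher numbered 640 at promoters and 70 elsewhere, and lower 667 and 5. Summits near Dbx numbered 0 within 5 kb and 7 within 50 kb. Against flanks the TAATTA ratio was 1.07 in the longest list and 1.09 with flanks at 500 bp, both short of the threshold, and 1.501 in peaks in all 3 replicates, 1.77 in the 500 highest and 1.36 to 1.47 with a replicate left out, all past it.

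These values turned direction, in at least 1 setting of each range given. Against 1.34% of bases the 5' UTR share was 1.36% in the longest list, 1.4% in the 500 highest and 1.37% with absent peaks put back. Against 18.9% of bases in 2R, 21.0% in 3L and 17.6% in X, in peaks in all 3 replicates 3L held 19.7% and X 18.4%, and in the 500 highest 2R held 18.4% and 3L 20%. With a replicate left out, 2R held 18.6% to 20.2%, 3L 19.9% to 20.2% and X 16.7% to 18.9%. Gene lists turn against the matched mean, which moves with the peak set. Muscle genes had 3.12% in the 500 highest (matched mean 4.69%) and 15.6% to 18.8% with a replicate left out (15.4% to 18.6%). Epidermis and trachea genes had 36.8% in the longest list (38.4%), as in the conservative list (31.9%), 10.5% in peaks in all 3 replicates (14.0%), 0.0% in the 500 highest (4.66%), 31.6% by gene body (37.0%) and 10.5% to 21.1% with a replicate left out (15.1% to 18.4%). Gut, fat body and blood genes had 25% within 1000 bp of a TSS (25.5%) and 15% with any replicate left out (15.2% to 18.2%). None of these lists passed in these settings. Against shuffled windows the ratio was 0.919 for TAATTA, 1.12 for TTTATGG, 0.947 for TGACAG, 1.19 for CACCTG, 1.13 for ATGCAAAT, 0.598 for CGCGCG and 0.886 for TTATAA. In peaks in all 3 replicates it was 0.943 for CAGCTG, 1.14 for ATGCAAAT and 0.842 for CGCGCG, and in the 500 highest 1.22 for TTTATGG, 0.846 for CAGCTG, 1.52 for ATGCAAAT and 0.783 for CGCGCG. With a replicate left out it ranged from 0.922 to 1.03 for TTTATGG, 0.956 to 1.15 for GAGAG, 0.962 to 1.12 for CAGCTG, 0.920 to 1.16 for ATGCAAAT and 0.953 to 1.49 for CGCGCG, on both sides of 1 in each. The cause was not tested.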

Other observations

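All tests in this part were chosen after the data were seen, and the genes it names, and the word AGGTGGCG, were picked from their values.

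Of 9 further gene lists, 5 passed the matched permutation test. Polycomb and Trithorax group genes had a summit at 11 of 20 (55.0%, matched median 25%, permutation adjusted p = 0.0366), with ph-p, Trl, osa and Psc at ranks 9, 14, 91 and 105. Genes of the ecdysone response had 9 of 13 (69.2%, matched median 38.5%, permutation adjusted p = 0.0421), with the nuclear receptors Hr3, EcR, Hr4 and usp at ranks 227, 381, 502 and 1154. Their share in the replicate lists was 61.5% ± 15.4 (SD, n = 3). Below their matched medians were cuticle genes with 4 of 114 (3.51%, permutation adjusted p = 0.0018), digestive proteases with 0 of 32 (permutation adjusted p = 0.0117) and odorant-binding proteins with 4 of 51 (7.84%, permutation adjusted p = 0.0421). Genes of the mitochondrial ribosome had 11 of 73 (15.1%, permutation adjusted p = 0.925), of the proteasome 14 of 48 (29.2%, 0.162), of translation initiation 16 of 44 (36.4%, 0.0774) and of insulators 4 of 10 (40%, 0.365), and none of these 4 passed.

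Some genes gathered many summits. Eip75B, an ecdysone-induced nuclear receptor, was nearest to 18 summits where its territory gave 4.14 (exact Poisson adjusted p = 9.53e-04), shn to 12 where it gave 1.76 (adjusted p = 9.53e-04), scyl to 11 where it gave 1.08 (adjusted p = 3.07e-04) and hry to 11 where it gave 1.31 (adjusted p = 8.51e-04). Peaks present in all 3 replicates held 3 of the summits at Eip75B, 2 at shn, 3 at scyl and 0 at hry. The Poisson test takes summits as independent and evenly spread over bases, so its p covers counting error only. Promoters held 51.4% of summits in 6.26% of bases, and the 4943 peaks merged into 4575 regions. Genes with many TSSs or overlapping peaks can therefore pass. AGGTGGCG was found at 4.65% of intergenic summits against 0.509% of their flanks, 1.39% against 0.497% for intronic summits and 0.826% against 0.610% for promoter summits. It is not a fixed word but came from the scan of 8 bp words at summits outside promoters, where it ranked 9. A higher share at intergenic and intronic summits follows in part from that choice. The words ranked above it there, with CACAGTGG at rank 1, were not split by class. In the fifth of peaks with the highest signal TAATTA had a share of 17.5% against 10.7% in flanks, and TTATAA, of the same bases, 17.2% against 8.91%. In the fifth with the lowest signal both lay below their flanks, TAATTA with 8.90% against 12.6% and TTATAA with 8.29% against 8.80%. These shares were not tested.

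Ribosomal protein genes that come as copies were compared in 2 tests, and neither passed. A summit was nearest to 9 of 16 genes whose symbol ends in a or b and to 54 of the other 69 (Fisher's exact p = 0.11). In 7 of 8 pairs of copies exactly 1 copy had a summit, where random assignment gave a mean of 4.18 (permutation p = 0.088).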
